A study of Mus musculus with 21 samples.

How the data were processed

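Total RNA of 21 libraries of mouse mammary organoids was sequenced after a stranded TruSeq preparation of polyadenylated RNA. The authors deposited a table of raw counts of reads or fragments per gene for 55536 Ensembl gene IDs, with no normalization. Per the labels, reads were assigned to genes of the mm10 genome with featureCounts, and DESeq2 was among the tools named. Tool versions were not stated, and the aligner, the strand setting and the annotation release are not given in the sources used here. The deposited table also holds, per the file headers, an other column with the gene length in bases. All 21 count columns were used. All gene IDs matched the GENCODE vM21 annotation with equal start and end, 36178 had a count in any library and 55450 had a transcript from which a GC content could be taken.

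Samples were grouped by genotype and day as the labels give them, into 6 groups of 3 original libraries. The labels put the original WT libraries in a first sequencing batch. The ATLD libraries and a resequenced run of replicate 1 of each WT day form the second. The median depth was 43114303 counts for the original WT libraries, 47580068 for the resequenced ones and 49512052 for the ATLD libraries. Mitochondrial transcripts held 2.52% to 4.44% of the counts of the original WT libraries and 2.31% to 3.43% of the ATLD libraries.

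Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15) and libraries scaled by TMM in edgeR 4.0.16 under R 4.3.3. Quasi-likelihood F tests, which are two-sided, were made with a Benjamini-Hochberg adjusted p under 0.05 as the threshold for a call. Fitted fold changes used a prior count of 0.125. The 6 comparisons of days and the 2 genotype by time contrasts used the 18 original libraries (18684 genes, 12 residual degrees of freedom). ATLD was compared with WT at each day in a fit of all 21 libraries with a batch term (18844 genes, 14 residual degrees of freedom). In that fit a resequenced run is not an independent culture. The batch term itself was significant for 44 genes, and 4838 had an unadjusted p under 0.05. It rests on the 3 WT cultures sequenced in both batches, so the 44 do not show that the batch effect was small.

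The comparisons, the tests, the 31 gene lists and the rule for named genes were fixed before the data were examined. The lists cover interferon-stimulated genes, the Ifi200 family, nucleic acid sensing, antigen presentation, p53 targets, break repair, the cell cycle, ERK and ERBB signalling, mammary cell types, milk, squamous genes, other cell types, secretion, NF-kB, immediate early genes, transition, junctions, unfolded proteins, cholesterol, hypoxia, matrix and mitochondrial transcripts. Each was tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members were counted as called over all genes tested and adjusted over the list alone. The named genes are Mre11a and Erbb2, and the 8 largest rises and 8 largest falls in each comparison, or 5 and 5 for day 28 against day 14 and for genotype by time. These had to be called, with a mean log2 CPM of at least 1, groups that do not overlap (except for genotype by time) and a symbol that is no predicted or clone name. Up to 4 members of each called list, and of the interferon, Ifi200 and p53 lists in every comparison, are named too. Levels of Spp1, Elf5, Vegfa, Mki67, Etv1 and other named genes are given for groups beside those in which the rule named them.

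The pipeline was tested on simulated data with 200 changed genes. It recovered 77% of 2-fold and 97% of 4-fold changes in WT day 14 against day 0, with 3.87% of the calls false. For ATLD day 28 against day 0 it recovered 79% and 91% with 8.11% false, above the threshold, and DESeq2 in WT day 14 against day 0 gave 13.3% false. In ATLD against WT at day 0 with the batch term it recovered 79% of 2-fold changes, and in the genotype by time contrast of day 14 it recovered 44%. Apart from the 200 genes and a batch effect, the day 0 simulation gave both genotypes equal means. Each resequenced run was drawn as a separate library. It thus does not test a comparison in which 55.6% of the genes are called, or runs that share a culture. With a GC trend simulated and no offset, 61% of 2-fold changes were recovered in WT day 14 against day 0. A changed list was called and 0 of 29 others were. The genes were simulated independently, so this does not test list calls where genes are correlated.

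Alternatives fixed in advance were median-of-ratios size factors, no filter, DESeq2 1.42.0, a fit of the compared groups alone, leaving out each replicate, a block for the replicate number, resequenced runs in place of originals, all libraries with a batch term, no batch term, the second batch alone and limma voom with the culture as random block. After the data were seen, offsets for GC content and for GC content with length were added, and a fit that leaves out 4 WT libraries picked by their measured GC trend. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.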

Results

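RNA of mouse mammary organoids grown from primary cells was sequenced before and after neuT was switched on. neuT is an activated rat form of the receptor tyrosine kinase gene Erbb2 and acts as an oncogene. The cultures were wild type (WT) or carried the ATLD1 allele of Mre11 (ATLD), named after ataxia-telangiectasia-like disorder. Mre11 is the nuclease of the Mre11-Rad50-Nbs1 complex, which binds DNA double-strand breaks. Each genotype was sampled at day 0, day 14 and day 28 of neuT activation, with 3 libraries for each of the 6 groups. Replicate 1 of each WT day was sequenced again together with the ATLD samples, which gave 3 more libraries. The original WT libraries held 30905703 to 50879106 counts, the resequenced ones 46532851 to 48887808 and the ATLD libraries 46331204 to 51757203. Levels below are counts per 1e+06 counts (CPM) after TMM scaling, as mean ± SD over the 3 original libraries of a group. Fold changes are log2 values ± SE from edgeR, with p-values adjusted over all genes tested. The labels do not say whether replicates came from separate animals, so the p-values measure a spread that may be technical. Between original WT replicates of a day alike in their GC trend, the SD of the log2 ratio over genes was 0.101 to 0.113. It was 0.181 to 0.591 between other original WT pairs and 0.233 to 0.375 between ATLD replicates. Between the runs of a WT culture it was 0.325, 0.636 and 0.143 at day 0, day 14 and day 28. The main fits shared the spread of a gene over all groups, so p-values need not mean the same in both genotypes.

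The main axis of variation separated the genotypes. The leading principal component held 66.2% of the variance and put all 12 WT libraries on the side opposite the 9 ATLD libraries. The next component held 12.6% and set the WT libraries of day 0 apart from those of the later days.

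**Figure D1:**
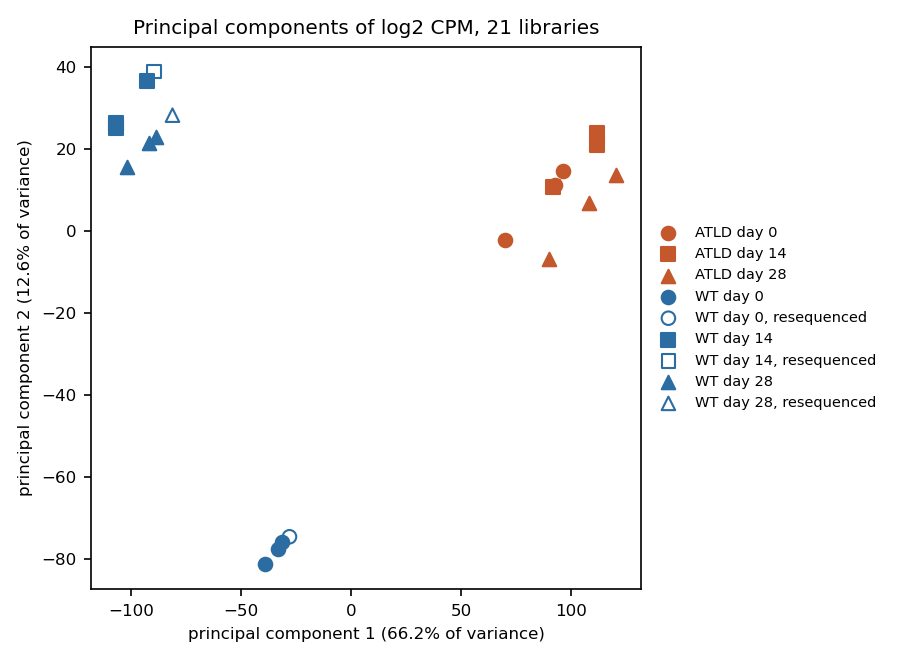
Principal components of log2 CPM of the 21 libraries, with component 1 (66.2% of the variance) on the x axis and component 2 (12.6%) on the y axis. Each point is a library, coloured by genotype and shaped by day, and open points are the 3 resequenced WT runs, which lie with their day.

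Mre11a, the mouse gene of Mre11 (ENSMUSG00000031928, mm10 chromosome 9, 14784654 to 14837123), was lower in every ATLD library than in every WT library. Its level was 55.5 ± 2.75 CPM in WT and 14.9 ± 0.725 CPM in ATLD at day 0. The range over all days was 42.2 to 58.6 CPM in the WT libraries and 14.1 to 17.1 CPM in the ATLD libraries. The ATLD minus WT log2 difference was -1.79 ± 0.11 at day 0, -1.63 ± 0.11 at day 14 and -1.47 ± 0.11 at day 28. Mre11a did not pass the test for a change with time in either genotype. Mouse Erbb2 (ENSMUSG00000062312, chromosome 11, 98412470 to 98437716) was at 89.7 ± 11.01 CPM in WT and 91.1 ± 19.97 CPM in ATLD at day 0. At day 28 it was at 112 ± 31.8 CPM and 85.3 ± 19.0 CPM. No time comparison called Erbb2, and it is not known whether reads of the rat transgene were counted in this gene. The WT day 14 replicate 1 culture had 69.0 CPM of Erbb2 in its original run and 146 CPM in the resequenced run. Day 14 replicates 1 and 3 and day 28 replicate 2, WT libraries with lower counts of GC-rich genes, had 69.0, 72.7 and 75.3 CPM. The other WT libraries of these days, resequenced ones included, had 127.7 to 146.1 CPM, and those of day 0 77.8 to 111 CPM. The WT levels of Erbb2 thus went with the GC trend. The ATLD minus WT difference of Erbb2 was -0.66 ± 0.27 at day 14 (adjusted p = 0.040) and -0.74 ± 0.28 at day 28 (adjusted p = 0.027). Both calls were lost in several alternatives, the fit without the batch term among them.

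The comparison of day 14 with day 0 in WT asks how WT organoids changed after neuT was switched on. No culture was kept to day 14 or day 28 without neuT, so in every comparison of days the time in culture and neuT cannot be told apart. Genes of luminal progenitor cells and of milk secretion fell strongly, while genes of low oxygen and glycolysis and of squamous skin-like differentiation rose. Csn3, the milk protein kappa-casein (ENSMUSG00000001622, chromosome 5, 87925579 to 87932665), went from 6072 ± 508 CPM to 18.9 ± 4.84 CPM, a log2 change of -8.33 ± 0.25. Elf5, a transcription factor of secretory luminal cells (ENSMUSG00000027186, chromosome 2, 103411688 to 103450989), went from 270 ± 7.10 CPM to 13.5 ± 2.79 CPM. Vegfa, a growth factor of blood vessels induced by low oxygen (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369), went from 15.1 ± 0.913 CPM to 245 ± 49.7 CPM. Of 18684 genes tested, 5666 were called, 2840 higher and 2826 lower, and 2831 of the calls were changes of at least 2-fold.

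All 15 luminal progenitor markers fell at WT day 14, over all genes and adjusted over the list alone (camera adjusted p = 4.00e-40). They include Ltf, the iron-binding milk protein lactoferrin, at -5.73 ± 0.15, Lcn2, lipocalin 2, at -4.39 ± 0.18, and Elf5 at -4.32 ± 0.15. Of 14 milk and secretory genes 13 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 2.43e-14). The riser was Spp1, osteopontin, which went from 172 ± 23.9 CPM to 1570 ± 148 CPM. Of 20 hypoxia and glycolysis genes 17 rose and 3 did not pass, and 18 rose adjusted over the list alone (adjusted p = 7.99e-21). Bnip3, a mitophagy receptor, rose by 3.53 ± 0.22 and Pfkp, a phosphofructokinase, by 2.76 ± 0.12. Of 20 squamous genes 15 rose and 1 fell, also adjusted over the list alone (adjusted p = 5.13e-09), with Krt6b, a keratin of stressed epidermis, at 5.07 ± 0.51 and Sprr1b, a cornified envelope protein, at 5.03 ± 0.56. These 4 lists were also called with an estimated correlation between genes.

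Basal and myoepithelial markers went both ways at WT day 14, with 7 of 20 higher and 9 lower, or 8 and 9 adjusted over the list alone. Among the members that fell were Acta2, smooth muscle actin, at -4.73 ± 0.17 and Tagln, transgelin, at -4.46 ± 0.19. The list was called lower (adjusted p = 0.00255), but adjusted p = 0.385 with an estimated correlation. Of 8 tested genes of the Ifi200 family, interferon-inducible DNA-binding proteins whose reads can be shared between members, 6 rose, also adjusted over the list alone (adjusted p = 0.00226). The adjusted p was 0.426 with an estimated correlation. The interferon-stimulated list was not called (adjusted p = 0.157), with 23 of 59 genes higher and 8 lower, or 27 and 8 adjusted over the list alone. p53 targets were not called either (adjusted p = 0.246), with 7 of 30 higher and 4 lower. Single members rose, such as Pmaip1, a pro-apoptotic BH3 protein, at 2.69 ± 0.16 and Cdkn1a, the cell cycle inhibitor p21, at 1.47 ± 0.11. No G2 and mitosis gene of 30 was called by edgeR (list adjusted p = 0.804), and Mki67 was at 388 ± 35.1 CPM and 331 ± 44.0 CPM. Outside the lists the largest rises were of Ndufa4l2, a hypoxia-induced mitochondrial protein, at 9.72 ± 0.75, Stmn2, a tubulin-binding protein, at 7.66 ± 0.26, and Hmga2, a chromatin protein of fetal tissues, at 6.67 ± 0.29. The largest falls beside Csn3 were of Cdh19, a cadherin, at -7.79 ± 0.32, and Crispld2, a secreted protein, at -6.95 ± 0.20. Of the day 14 WT libraries 2 of 3 had lower counts of GC-rich genes, and with this trend removed, a choice made after seeing the data, the basal list was not called (adjusted p = 0.126).

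**Figure D2:**
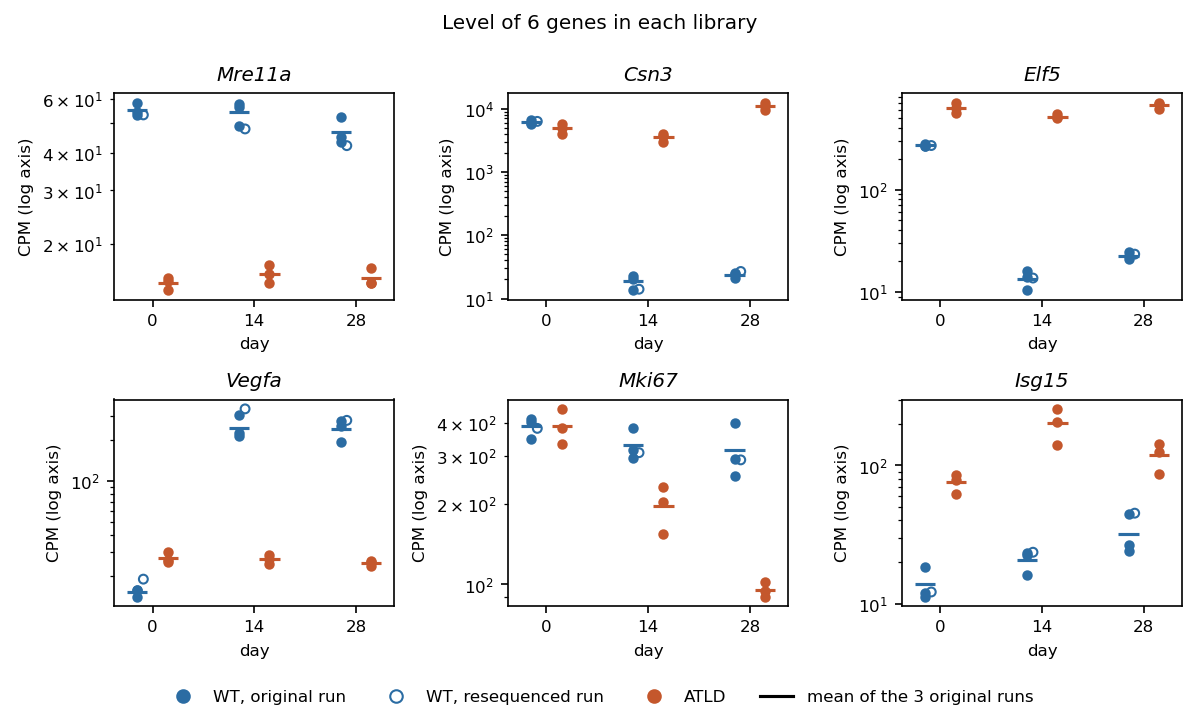
CPM on a log axis against day for Mre11a, Csn3, Elf5, Vegfa, Mki67 and Isg15 in each library. Filled points are original libraries, open points the resequenced WT runs and bars the mean of 3 original libraries. Csn3 averaged 18.9 CPM in WT and 3563 CPM in ATLD at day 14.

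At day 28 against day 0 in WT the luminal progenitor and milk genes were still low and the hypoxia and squamous genes still high. Csn3 was at 23.7 ± 2.03 CPM, a log2 change of -8.00 ± 0.25, and Vegfa at 238 ± 42.2 CPM, a change of 3.98 ± 0.16. Cdh19 changed by -8.53 ± 0.35 and Stmn2 by 7.44 ± 0.26. edgeR called 4621 genes, 2303 higher and 2318 lower, and 2518 by at least 2-fold. All 15 luminal progenitor markers fell, also adjusted over the list alone (adjusted p = 7.55e-45). Of 14 milk genes 12 fell and 1 rose, also adjusted over the list alone (adjusted p = 8.00e-15). Of 20 hypoxia genes 17 rose, and all 20 adjusted over the list alone (adjusted p = 1.07e-20). Of 20 squamous genes 13 rose and 1 fell, or 15 and 1 adjusted over the list alone (adjusted p = 1.32e-06). These 4 calls held with an estimated correlation.

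Further lists were called at WT day 28 with the preset correlation and lost with an estimated one. Of 59 interferon-stimulated genes 27 rose and 5 fell, or 29 and 5 adjusted over the list alone (adjusted p = 0.00570, and adjusted p = 0.705 with an estimated correlation). Ifi27l2a, an interferon-inducible membrane protein, rose by 3.13 ± 0.44. The Ifi200 family had 6 of 8 genes higher, or 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.0109, and adjusted p = 0.486 with an estimated correlation). MHC class II genes had 4 of 7 higher, or 4 higher and 1 lower adjusted over the list alone, led by H2-Ab1 at 3.58 ± 0.25 and its chaperone Cd74 at 2.06 ± 0.24, both at low levels in libraries that also held lung transcripts (adjusted p = 0.0172, and adjusted p = 0.446 with an estimated correlation). Of 38 genes of break repair and checkpoint 14 fell and 2 rose, or 15 and 2 adjusted over the list alone (adjusted p = 0.0367, and adjusted p = 0.664 with an estimated correlation). Fanca, of the Fanconi anaemia pathway, changed by -1.11 ± 0.18. Of 30 S phase genes 9 fell, also adjusted over the list alone (adjusted p = 0.0272, and adjusted p = 0.664 with an estimated correlation). ERBB receptors and ligands had 5 of 12 lower and 1 higher, or 6 and 1 adjusted over the list alone (adjusted p = 0.0171, and adjusted p = 0.312 with an estimated correlation), with Nrg2, a neuregulin, at -2.60 ± 0.23. Of 18 unfolded protein response genes 11 fell, or 12 adjusted over the list alone (adjusted p = 0.0177, and adjusted p = 0.0865 with an estimated correlation). Extracellular matrix genes had 7 of 20 higher and 1 lower, or 8 and 1 adjusted over the list alone (adjusted p = 0.0367, and adjusted p = 0.705 with an estimated correlation), with Mmp9, a matrix metalloproteinase, at 5.84 ± 0.46.

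Between day 28 and day 14 in WT few genes differed. Acta2 was higher at day 28 by 1.18 ± 0.15 and Elf5 by 0.74 ± 0.13, while Krt6a, a stress keratin, was lower by a log2 change of -0.87 ± 0.14. edgeR called 169 genes, 99 higher and 70 lower. The count fell to 0 when the spread was estimated from these 6 libraries alone, where 1114 genes had an unadjusted p under 0.05 and DESeq2 on all libraries called 316. It rose to 3817 without WT day 14 replicate 2, and was 72 without day 14 replicate 1, 80 without day 14 replicate 3, 62 without day 28 replicate 1 and 67 without day 28 replicate 3. Squamous genes were the list called lower with an estimated correlation too, with 2 of 20 lower, or 6 adjusted over the list alone (adjusted p = 1.41e-06).

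The other lists called between WT day 28 and day 14 were lost with an estimated correlation. Basal markers had 5 of 20 higher, or 7 adjusted over the list alone (adjusted p = 1.18e-08, and adjusted p = 0.0649 with an estimated correlation). Immediate early genes had 6 of 20 higher, or 7 adjusted over the list alone, among them Nr4a1 at 1.26 ± 0.25 and Egr2 at 1.01 ± 0.13, both transcription factors (adjusted p = 9.28e-09, and adjusted p = 0.1996 with an estimated correlation). Luminal progenitor markers had 2 of 15 higher and 1 lower, or 3 and 1 adjusted over the list alone (adjusted p = 0.0129, and adjusted p = 0.213 with an estimated correlation). The 9 mitochondrially encoded transcripts had no member called by edgeR, and all 9 were lower adjusted over the list alone (adjusted p = 5.25e-08, and adjusted p = 0.213 with an estimated correlation). The share of the counts held by all mitochondrial genes, not these 9 alone, was 4.44% and 4.37% in the 2 day 14 libraries with lower counts of GC-rich genes and 2.87% in the third. At day 28 it was 3.66% in the library with that trend and 2.64% and 2.61% in the others. The median log2 change of the 9 list genes was -0.44, and -0.23 with the trend removed. Fibroblast markers had none of 13 called, and 5 higher adjusted over the list alone (adjusted p = 9.88e-05, and adjusted p = 0.1996 with an estimated correlation). Hypoxia genes had 2 of 20 lower, or 4 adjusted over the list alone (adjusted p = 0.00534, and adjusted p = 0.346 with an estimated correlation). Transition genes had 1 of 15 higher, or 2 adjusted over the list alone (adjusted p = 0.0115, and adjusted p = 0.213 with an estimated correlation), and matrix genes 1 of 20, also adjusted over the list alone (adjusted p = 0.0229, and adjusted p = 0.673 with an estimated correlation). The interferon-stimulated and MHC class I lists were called higher, and the Ifi200 and cholesterol lists lower, with no member called by edgeR. Their adjusted p was 0.00454, 0.0407, 0.0266 and 0.0389, and 0.678, 0.673, 0.528 and 0.346 with an estimated correlation. With the GC trend removed, a choice made after seeing the data, the MHC class I, Ifi200 and matrix lists were not called (adjusted p = 0.396, 0.373 and 0.234). The 8 macrophage and myeloid genes tested had no member called by edgeR and 1 higher adjusted over the list alone (adjusted p = 0.0229, and adjusted p = 0.213 with an estimated correlation). This list holds Lyz2, lysozyme of myeloid cells, singled out after its values were seen, at 4.26 to 9.06 CPM in the original WT runs and at most 0.0401 CPM in the resequenced ones.

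The comparison of day 14 with day 0 in ATLD asks the same question for organoids with the Mre11 allele. Here the lists of cell division, DNA replication and break repair fell and senescence-associated secretion rose. The interferon-stimulated list was called higher too, with 24 of 59 genes up, but adjusted p = 0.347 with an estimated correlation. Mki67, a marker of cycling cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), went from 389 ± 58.3 CPM to 196 ± 38.3 CPM, a log2 change of -0.99 ± 0.17. Isg15, a ubiquitin-like protein induced by interferon (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), went from 75.4 ± 11.99 CPM to 202 ± 58.2 CPM, a change of 1.42 ± 0.27. Il6, an inflammatory cytokine, rose by 3.36 ± 0.28 from a low level and Mmp9 by 5.28 ± 0.44. The largest rise was of Pde3a, a cyclic nucleotide phosphodiesterase, from 0.0147 ± 0.0127 CPM to 4.59 ± 0.364 CPM. edgeR called 2180 genes, 968 higher and 1212 lower, and 817 by at least 2-fold. With the GC trend removed, a choice made after seeing the data, it called 3709.

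All 30 G2 and mitosis genes fell at ATLD day 14, also adjusted over the list alone (adjusted p = 9.75e-30). Of 30 S phase genes 23 fell, or 27 adjusted over the list alone (adjusted p = 2.55e-18), with Rrm2, a ribonucleotide reductase subunit, at -1.03 ± 0.12. Of 38 break repair and checkpoint genes 17 fell, or 22 with 1 higher adjusted over the list alone (adjusted p = 2.01e-11). Polq, the polymerase of end joining at short homologies, changed by -1.09 ± 0.18. Cholesterol synthesis had 11 of 20 genes lower, or 13 adjusted over the list alone (adjusted p = 2.42e-07). Senescence-associated secretion had 10 of 22 higher and 2 lower, or 10 and 5 adjusted over the list alone (adjusted p = 1.83e-07). Squamous genes had 6 of 20 lower and 1 higher, or 8 and 1 adjusted over the list alone (adjusted p = 0.000744). These 6 calls held with an estimated correlation. Interferon-stimulated genes had 24 of 59 higher and none lower, or 37 higher adjusted over the list alone (adjusted p = 6.64e-13, and adjusted p = 0.347 with an estimated correlation). Usp18, a protease that removes Isg15, rose by 1.27 ± 0.27. NF-kB targets were called lower, with 5 of 20 lower and 1 higher, or 10 and 1 adjusted over the list alone (adjusted p = 0.00151, and adjusted p = 0.347 with an estimated correlation). The Ifi200 family had 5 of 8 higher, also adjusted over the list alone (adjusted p = 1.83e-07, and adjusted p = 0.102 with an estimated correlation). Genes of epithelial-mesenchymal transition had 6 of 15 higher and 1 lower, or 9 and 1 adjusted over the list alone, with Zeb1, a transcription factor, at 2.47 ± 0.43 (adjusted p = 0.00147, and adjusted p = 0.102 with an estimated correlation). Luminal progenitor markers were not called (adjusted p = 0.0826), with 2 of 15 higher and 3 lower, and hypoxia genes were not called (adjusted p = 0.0830), with 4 of 20 higher and 2 lower. With median-of-ratios size factors and the preset correlation, basal and myoepithelial markers had 7 of 20 lower and 3 higher (camera adjusted p = 0.0263).

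At day 28 against day 0 in ATLD the fall of cell cycle genes was larger. Mki67 was at 95.8 ± 6.09 CPM, a log2 change of -2.02 ± 0.18, and Cenpf, a kinetochore protein, changed by -2.20 ± 0.21. Brca1, a tumour suppressor of recombination repair, changed by -1.88 ± 0.13. Fos and Fosb, subunits of the transcription factor AP-1, changed by -2.20 ± 0.19 and -4.19 ± 0.48. Csn3 rose to 11000 ± 1559 CPM, a change of 1.17 ± 0.18. edgeR called 5568 genes, 2634 higher and 2934 lower, and 2173 by at least 2-fold. All 30 G2 and mitosis genes fell (adjusted p = 4.44e-56) and 29 of 30 S phase genes (adjusted p = 1.10e-33), both also adjusted over the list alone. Of 38 break repair genes 26 fell, or 30 adjusted over the list alone (adjusted p = 1.60e-17). Cholesterol synthesis had 15 of 20 lower, or 16 adjusted over the list alone (adjusted p = 1.83e-06). These 4 calls held with an estimated correlation. Immediate early genes had 12 of 20 lower and 2 higher, also adjusted over the list alone (adjusted p = 1.80e-05, and adjusted p = 0.354 with an estimated correlation). NF-kB targets had 11 of 20 lower and 2 higher, or 12 and 2 adjusted over the list alone (adjusted p = 0.00155, and adjusted p = 0.354 with an estimated correlation), with the chemokine Ccl20 at -2.38 ± 0.19. Squamous genes had 9 of 20 lower and 2 higher, also adjusted over the list alone (adjusted p = 0.00729, and adjusted p = 0.117 with an estimated correlation). Interferon-stimulated genes were not called (adjusted p = 0.582), with 11 of 59 higher and 11 lower.

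From day 14 to day 28 in ATLD the lists of cell division and senescence-associated secretion fell and milk genes rose. The interferon-stimulated list was called lower, but adjusted p = 0.502 with an estimated correlation. Cxcl10, an interferon-induced chemokine, changed by -1.94 ± 0.50 and Il6 by -2.48 ± 0.26. Ltf rose by 2.18 ± 0.13, from 2484 ± 333 CPM to 11230 ± 1146 CPM, and Csn3 by 1.63 ± 0.19. edgeR called 3232 genes, 1542 higher and 1690 lower, and 5129 with the GC trend removed. G2 and mitosis had 29 of 30 genes lower, also adjusted over the list alone (adjusted p = 1.68e-28), and S phase 24 of 30, or 26 adjusted over the list alone (adjusted p = 1.36e-16). Milk genes had 8 of 14 higher and 1 lower, also adjusted over the list alone (adjusted p = 7.00e-07). Senescence-associated secretion had 12 of 22 lower and 2 higher, or 14 and 3 adjusted over the list alone (adjusted p = 7.91e-07). These 4 calls held with an estimated correlation. Interferon-stimulated genes had 25 of 59 lower and none higher, or 33 lower adjusted over the list alone (adjusted p = 2.69e-08, and adjusted p = 0.502 with an estimated correlation). MHC class I genes had 10 of 18 lower, or 11 adjusted over the list alone (adjusted p = 1.37e-06, and adjusted p = 0.328 with an estimated correlation). Mitochondrially encoded transcripts had 2 of 9 lower, or 4 adjusted over the list alone (adjusted p = 0.0211, and adjusted p = 0.566 with an estimated correlation), a call also lost with the GC trend removed.

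**Figure D3:**
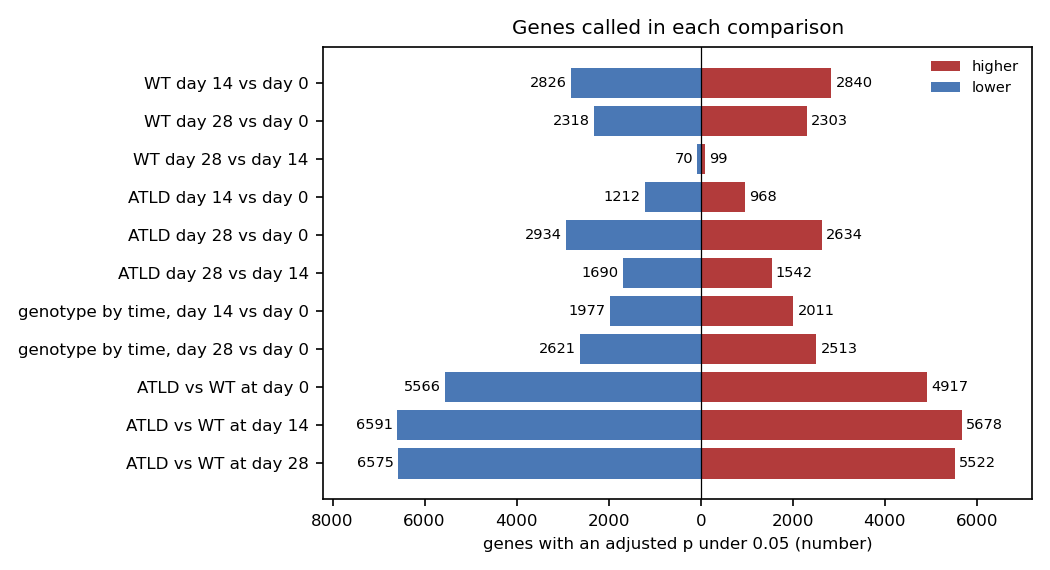
Number of genes with an adjusted p under 0.05 in each of the 11 comparisons, with genes higher to the right of 0 and genes lower to the left. WT day 28 against day 14 had 169 calls and ATLD against WT at day 14 had 12269.

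The genotype by time contrast asks whether the change after neuT was switched on differed between ATLD and WT, as the ATLD change minus the WT change. The difference was positive for luminal progenitor and milk genes, which fell in WT, and negative for hypoxia and squamous genes, which rose in WT. It was negative for genes of cell division, which fell in ATLD. With an estimated correlation the division list had an adjusted p = 0.466 at day 14 and the hypoxia list an adjusted p = 0.0785 at day 28. For Csn3 the difference was 7.87 ± 0.29 at day 14 and 9.17 ± 0.30 at day 28. For Vegfa, whose ATLD group means were 24.8 to 27.1 CPM, it was -4.06 ± 0.21 and -4.10 ± 0.21. Etv1, a transcription factor downstream of ERK, and Spry4, an inhibitor of ERK signalling, differed by 5.24 ± 0.25 and 4.43 ± 0.24 at day 14. Pmaip1 differed by -2.52 ± 0.22 and Cdkn1a by -1.41 ± 0.16 at day 14, while the p53 target list was not called (adjusted p = 0.154), with 1 of 30 positive and 4 negative. edgeR called 3988 genes at day 14, 2011 higher and 1977 lower, and 5134 at day 28, 2513 higher and 2621 lower.

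At day 14 the difference was positive for 11 of 15 luminal progenitor markers, or 12 adjusted over the list alone (adjusted p = 3.44e-34), and for 10 of 14 milk genes, or 11 adjusted over the list alone (adjusted p = 4.05e-13). It was negative for 12 of 20 squamous genes, or 15 adjusted over the list alone (adjusted p = 2.26e-11), and for 13 of 20 hypoxia genes, or 14 adjusted over the list alone (adjusted p = 2.20e-14). These 4 calls held with an estimated correlation. It was negative for 24 of 30 G2 and mitosis genes, or 27 adjusted over the list alone (adjusted p = 9.27e-07, and adjusted p = 0.466 with an estimated correlation). At day 28 it was positive for 12 of 15 luminal progenitor markers, or 13 adjusted over the list alone (adjusted p = 3.50e-33), and for 12 of 14 milk genes, also adjusted over the list alone (adjusted p = 2.88e-17). It was negative for 12 of 20 squamous genes with 1 positive, or 13 and 1 adjusted over the list alone (adjusted p = 5.97e-08), and for all 30 G2 and mitosis genes, also adjusted over the list alone (adjusted p = 3.09e-21). These 4 calls held too. The hypoxia list at day 28 had 11 of 20 negative and 1 positive, or 12 and 1 adjusted over the list alone (adjusted p = 1.82e-08, and adjusted p = 0.0785 with an estimated correlation). ERK feedback targets had 10 of 23 positive and 3 negative at day 14, or 10 and 4 adjusted over the list alone (adjusted p = 0.0122, and adjusted p = 0.541 with an estimated correlation). Interferon-stimulated genes were not called in either contrast, but at day 14 they were (adjusted p = 0.0109) with 4 WT libraries left out for their GC trend, a choice made after seeing the data.

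Genes called in both genotypes included changes in equal and in opposite directions. At day 14, 268 genes rose in both genotypes and 340 fell in both, where 147 and 183 would be shared if the calls were independent. Another 340 rose in WT and fell in ATLD, and 350 fell in WT and rose in ATLD, against 184 and 146. Across the 18684 genes Pearson's correlation of the changes was -0.043 at day 14 and -0.078 at day 28, where genes are not independent replicates.

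**Figure D4:**
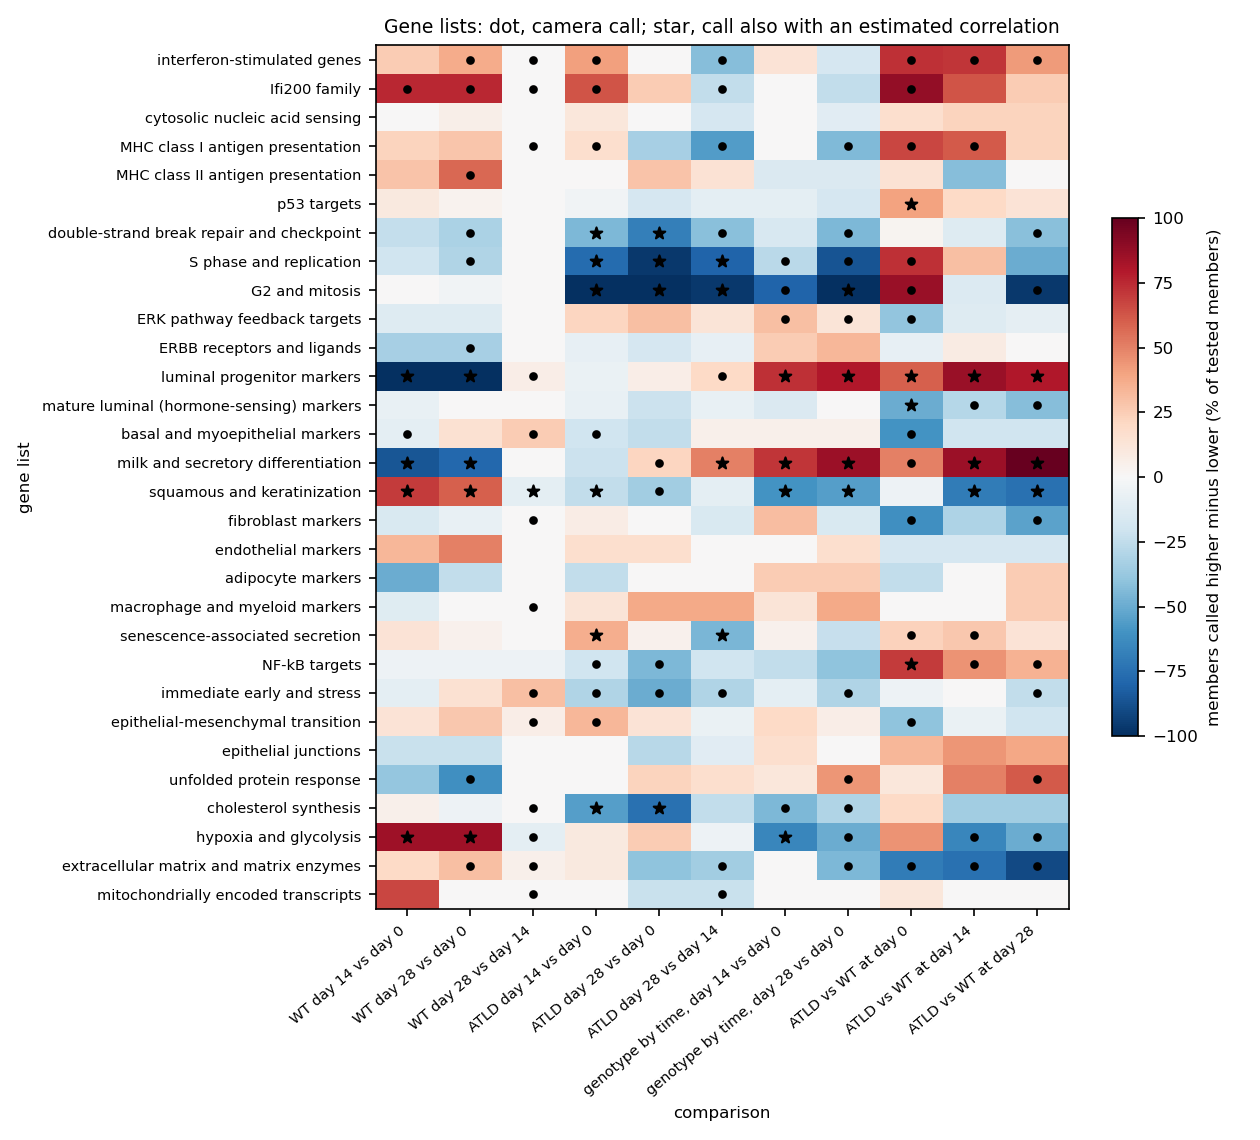
Gene lists (y axis) in the 11 comparisons (x axis), coloured by the number of members called higher minus the number called lower, as a percentage of the members tested. A dot marks a camera call and a star a call kept with an estimated correlation. All 15 luminal progenitor markers fell in WT at day 14 and day 28.

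ATLD was compared with WT at each day in a fit of all 21 libraries with a term for the sequencing batch, which the resequenced WT runs link across. At day 0, before neuT was switched on, NF-kB targets, luminal progenitor markers and p53 targets were higher in ATLD and hormone-sensing luminal markers lower. Interferon, MHC class I and division lists were called higher, and basal and fibroblast lists lower, but with adjusted p = 0.317, 0.317, 0.317, 0.281 and 0.306 with an estimated correlation. Foxa1, a transcription factor that opens chromatin for the oestrogen receptor (ENSMUSG00000035451, chromosome 12, 57540628 to 57546916), was at 115 ± 1.87 CPM in WT and 3.94 ± 1.43 CPM in ATLD, a log2 difference of -5.00 ± 0.21. Esr1, the oestrogen receptor, differed by -2.26 ± 0.18. B2m, the light chain of MHC class I, was higher by 1.59 ± 0.17, and the chemokines Ccl20 and Ccl2 by 4.49 ± 0.26 and 3.25 ± 0.20. Of 18844 genes tested 10483 were called, 4917 higher and 5566 lower. By at least 2-fold 1662 were higher and 3449 lower. The day 0 libraries had counts for 25425 to 26502 genes in WT, the resequenced run included, and for 23788 to 24537 in ATLD. The make-up of cell types in the cultures was not measured. The count of all calls was 6927 without WT day 0 replicate 1, the library that links the batches at this day.

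At day 0 the hormone-sensing list had 9 of 14 genes lower and 2 higher (adjusted p = 5.70e-05). NF-kB targets had 15 of 20 higher and 1 lower (adjusted p = 8.00e-10), luminal progenitor markers 11 of 15 higher and 2 lower (adjusted p = 0.000101), and p53 targets 14 of 30 higher and 2 lower (adjusted p = 0.00791), with Fas, a death receptor, at 1.48 ± 0.15. Counts adjusted over the list alone were equal for these 4 lists, and their calls held with an estimated correlation. Interferon-stimulated genes had 43 of 59 higher and none lower, or 44 and 1 adjusted over the list alone (adjusted p = 5.66e-11, and adjusted p = 0.317 with an estimated correlation). MHC class I had 13 of 18 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.000150, and adjusted p = 0.317 with an estimated correlation). G2 and mitosis had 26 of 30 higher, or 27 adjusted over the list alone (adjusted p = 5.57e-06, and adjusted p = 0.317 with an estimated correlation). Basal markers had 14 of 20 lower and 2 higher, also adjusted over the list alone (adjusted p = 0.000957, and adjusted p = 0.281 with an estimated correlation). Fibroblast markers had 8 of 13 lower, also adjusted over the list alone, with the collagen Col6a3 at -6.33 ± 0.51 (adjusted p = 0.00326, and adjusted p = 0.306 with an estimated correlation). ERK feedback targets had 12 of 23 lower and 3 higher, or 12 and 5 adjusted over the list alone (adjusted p = 0.0162, and adjusted p = 0.416 with an estimated correlation).

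At day 14 the luminal progenitor and milk genes were far higher in ATLD than in WT and the squamous genes lower. Csn3 differed by 7.70 ± 0.26, Ltf by 6.44 ± 0.15, Krt6a by -4.98 ± 0.16 and Vegfa by -3.58 ± 0.16. Il6 was at 2.29 ± 0.165 CPM in ATLD and 0.0568 ± 0.0179 CPM in WT. edgeR called 12269 genes, 5678 higher and 6591 lower. By at least 2-fold 2648 were higher and 4443 lower. The count of all calls was 7917 when only the 7 libraries of that day were fitted. Luminal progenitor markers had 13 of 15 higher (adjusted p = 1.03e-27), milk genes 12 of 14 higher (adjusted p = 1.12e-10), and squamous genes 17 of 20 lower and 3 higher (adjusted p = 3.24e-08). Counts adjusted over the list alone were equal, and the calls held with an estimated correlation. Interferon-stimulated genes had 44 of 59 higher and 2 lower, also adjusted over the list alone (adjusted p = 1.40e-09, and adjusted p = 0.513 with an estimated correlation). Hypoxia genes had 13 of 20 lower, also adjusted over the list alone (adjusted p = 4.82e-06, and adjusted p = 0.201 with an estimated correlation). G2 and mitosis genes were not called (adjusted p = 0.934). Senescence-associated secretion had 13 of 22 higher and 7 lower (adjusted p = 0.0329, and adjusted p = 0.450 with an estimated correlation), a call lost with the GC trend removed (adjusted p = 0.080).

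At day 28 all 14 milk genes were higher in ATLD and 17 of 20 squamous genes lower. Csn3 differed by 8.85 ± 0.27 and Ltf by 8.66 ± 0.17. Mki67 was at 315 ± 76.0 CPM in WT and 95.8 ± 6.09 CPM in ATLD, a log2 difference of -1.63 ± 0.18. Brca1 differed by -1.57 ± 0.14, and Lama3, a laminin chain of the basement membrane, by -3.85 ± 0.35. edgeR called 12097 genes, 5522 higher and 6575 lower, and by at least 2-fold 2306 were higher and 4549 lower. Milk genes (adjusted p = 8.46e-15), luminal progenitor markers with 12 of 15 higher (adjusted p = 9.72e-30) and squamous genes with 17 of 20 lower and 2 higher (adjusted p = 1.30e-06) were called with an estimated correlation too, with equal counts adjusted over the list alone. G2 and mitosis had 29 of 30 lower, with an adjusted p = 9.94e-05, and adjusted p = 0.499 with an estimated correlation. Extracellular matrix genes had 19 of 20 lower and 1 higher, also adjusted over the list alone (adjusted p = 0.000129, and adjusted p = 0.518 with an estimated correlation). With median-of-ratios size factors and the preset correlation, fibroblast markers had 8 of 13 lower and 1 higher (camera adjusted p = 0.0149). Hormone-sensing luminal markers there had 9 of 14 lower and 3 higher (camera adjusted p = 0.00271). Break repair genes had 23 of 38 lower and 7 higher, or 24 and 7 adjusted over the list alone (adjusted p = 0.0115, and adjusted p = 0.566 with an estimated correlation). Interferon-stimulated genes had 34 of 59 higher and 9 lower, or 35 and 9 adjusted over the list alone (adjusted p = 0.00269, and adjusted p = 0.714 with an estimated correlation).

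Some lists were called in no comparison with TMM scaling and the preset correlation. The lowest adjusted p was 0.373 for cytosolic nucleic acid sensing and 0.204 for epithelial junctions, both in ATLD against WT at day 0. With the GC trend removed, a choice made after seeing the data, epithelial junctions were called in 7 comparisons, among them ATLD against WT at day 0 (9 of 18 higher and 2 lower, adjusted p = 0.00459) and WT day 28 against day 0 (2 higher and 7 lower, adjusted p = 0.0311). The lowest was 0.610 for the 6 endothelial markers tested, in ATLD day 14 against day 0, and 0.190 for the 4 adipocyte markers tested, in WT day 28 against day 0. Of 15 lymphocyte markers 2 had enough counts to be tested, and the list had no camera test.

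**Figure D5:**
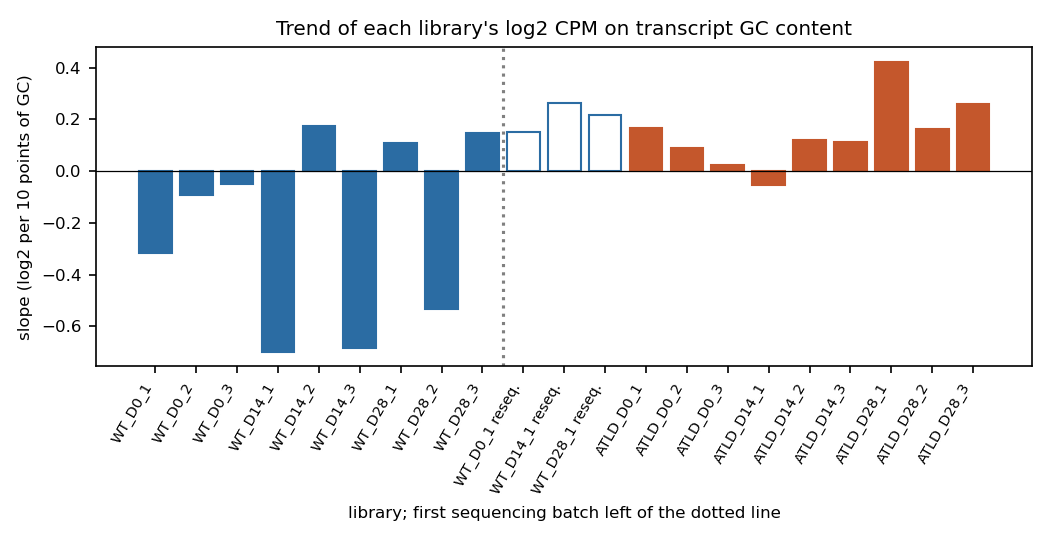
Slope of log2 CPM, relative to the mean of the 21 libraries, on transcript GC content (log2 units per 10 percentage points) for each library, with the original WT libraries to the left of the dotted line. Filled bars are original libraries and open bars resequenced WT runs. WT day 14 replicate 1 had a slope of -0.70 in its original run and 0.27 when resequenced.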

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

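The tests of the GC pattern were chosen after the result was seen, while the splits of the samples were planned. Tests of the difference between genotypes set apart the results of this paragraph. The change with time differed between ATLD and WT for 3988 genes at day 14 and 5134 genes at day 28 by edgeR. At day 14 the adjusted p of the difference was 3.438e-34 for luminal progenitor markers, 4.048e-13 for milk and secretory genes, 2.203e-14 for hypoxia and glycolysis and 2.263e-11 for squamous genes. It was 9.269e-07 for G2 and mitosis, 0.02271 for S phase, 0.01218 for ERK feedback targets and 0.03764 for cholesterol synthesis, calls lost with an estimated correlation (adjusted p = 0.466, 0.658, 0.541 and 0.466). At day 28 it was 3.503e-33 for luminal progenitor markers, 2.876e-17 for milk genes, 3.092e-21 for G2 and mitosis and 5.971e-08 for squamous genes. These 4, and the first 4 of day 14, were also called with an estimated correlation. It was 3.188e-09 for S phase and 1.822e-08 for hypoxia, calls lost with an estimated correlation (adjusted p = 0.154 and 0.0785). For break repair and checkpoint it was 0.0001897, for immediate early genes 0.0005302, for ERK feedback targets 0.01324 and for MHC class I 0.01408, all lost with an estimated correlation (adjusted p = 0.275, 0.381, 0.436 and 0.646). For cholesterol synthesis and for extracellular matrix it was 0.01894 each, and for the unfolded protein response 0.01993, also lost (adjusted p = 0.275, 0.662 and 0.0985 with an estimated correlation).

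The same samples were split into other groups of equal sizes and refitted with edgeR. For the genotype by time contrasts, 1 of 50 splits, the real one, gave as many genes at each day. The real values were 3988 and 5134, and the highest of the other splits were 3197 and 1636. These splits do not settle whether chance can be excluded, since they mix libraries of different days, whose change with time then adds to the spread within groups. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real value was 5666 for WT day 14 against day 0, 4621 for WT day 28 against day 0, 2180 for ATLD day 14 against day 0, 5568 for ATLD day 28 against day 0 and 3232 for ATLD day 28 against day 14. It was 10483, 12269 and 12097 for ATLD against WT at day 0, day 14 and day 28. In each of these 8 comparisons the highest other split gave 0. For WT day 28 against day 14 the real value was 169 and the highest other 7906, so 2 of the 10 splits gave as many. That split sets day 14 replicates 1 and 3 and day 28 replicate 2 against the other 3 libraries, which points to a structure of the samples.

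Counts of GC-rich genes were lower in 4 of the 9 original WT libraries, replicate 1 of day 0, replicates 1 and 3 of day 14 and replicate 2 of day 28. GC content explained at least 74.85% of the variance of the log2 ratio of each to a library without the trend, over 11109 genes, but these libraries were picked by their slope, so the share does not count for a GC content bias of the original run, which stays open. A difference between cultures is argued against for day 0 replicate 1 and day 14 replicate 1, if the resequenced runs are of the same cultures as labelled, which the values do not show, since these runs correlated more with other libraries of the day (0.9937 and 0.9941) than with their own originals (0.9911 and 0.98), as the trend itself would give. They had slopes of 0.152 and 0.265, above the lowest of the day's other original libraries without the trend (-0.091 and 0.176), where the originals had -0.316 and -0.698. For day 14 replicate 3 and day 28 replicate 2 a bias and a culture difference cannot be told apart, since no rerun exists. Their shifts had Spearman correlations of 0.946 and 0.952 across genes with that between the runs of day 14 replicate 1, where a culture difference was predicted to give under 0.3. These libraries were picked by their slope, which favours a high value. The shift between the runs of day 28 replicate 1, which lack the trend, gave 0.563, so the test does not decide. A culture difference that itself follows GC content would not be seen by that test.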

How the results depend on the processing

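The offsets for GC content and length and the fit without the 4 low-GC-trend WT libraries were chosen after seeing the data, and the cause of the changes below was not tested except where fewer libraries were fitted. The 169 calls of WT day 28 against day 14 became 316 with DESeq2, 0 with only the compared groups (1114 at an unadjusted p under 0.05), 94 with resequenced runs in place of originals, 321 with the GC offset and 403 with GC and length. With a replicate block they became 55, and the calls of ATLD day 28 against day 14 went from 3232 to 1975. The labels do not say whether the replicate numbers pair the samples across days. Deviations from the group means correlated at -0.967 to 0.846 between same-numbered WT libraries and at -0.86 to 0.596 between ATLD ones, which does not settle it. ATLD day 28 against day 14 gave 5129 with the GC offset, 5584 with GC and length and 5115 without the low-GC-trend libraries. ATLD day 14 against day 0 gave 3709 and 4046 with the offsets, and ATLD against WT at day 14 gave 7917 with only the compared groups. Of 330 list tests 125 were calls, and 41 with an estimated correlation.

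Leaving out each replicate gave 4456 to 8242 calls for WT day 14 against day 0, 3733 to 4508 for WT day 28 against day 0, 62 to 3817 for WT day 28 against day 14 (3817 without day 14 replicate 2), 1629 to 1901 for ATLD day 14 against day 0, 4478 to 5074 for ATLD day 28 against day 0 and 2202 to 2677 for ATLD day 28 against day 14. For genotype by time it gave 3308 to 5672 at day 14 and 4375 to 4976 at day 28. For ATLD against WT it gave 6927 to 10784 at day 0 (6927 without WT day 0 replicate 1), 9722 to 12751 at day 14 and 9856 to 12054 at day 28. Csn1s2a in ATLD against WT at day 0 changed direction without WT day 0 replicate 1 (log2 -0.20, adjusted p = 0.859), its log2 value being at most 1.79 with another replicate left out. The mitochondrial list in ATLD day 28 against day 14 did so with GC and length (adjusted p = 0.978), and the Ifi200 list in WT day 28 against day 14 without the low-GC-trend libraries (adjusted p = 0.835). Of 671 named results, 1 lost its call with median-of-ratios factors, 5 with no filter, 0 with DESeq2, 27 with a replicate block, 0 with the GC offset, 4 with GC and length and 13 without the low-GC-trend libraries. Calls were lost for 33 of 663 with only the compared groups, 12 of 272 with resequenced runs in place of originals, 3 of 213 without a batch term, 4 of 213 with the second batch alone, 2 of 213 with voom and 174 of 4776 over the fits that leave out a replicate. The voom fit estimated a correlation of -0.181 between runs of a culture. A negative value does not allow for such runs being alike, so that fit does not test the effect of counting a culture again.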

Other observations

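The tests in this part were chosen after the results were seen. CPM in this part are by the total counts, without TMM scaling.

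Transcripts of lung were present at low levels in the original WT libraries. Sftpc, a lung surfactant protein, averaged 7.16 CPM there (4.45 to 11.7) and Lyz2, lysozyme of myeloid cells, 6.41 CPM (4.64 to 9.97). Genes with at most 0.2 CPM in every ATLD library are called silent here, 9 of 15 lung epithelial genes and 11 of 15 immune genes, while 6 and 4 were also expressed in ATLD. The silent lung genes summed to 7.81 to 17.6 CPM in the original WT libraries, 0.860 to 1.16 CPM in the resequenced runs and at most 0.290 CPM in ATLD. The silent immune genes summed to 7.33 to 14.7 CPM, 0.0215 to 0.189 CPM and at most 0.307 CPM. The ratio of the sums was 1.03 to 1.42 over the 9 original libraries, and the 11 of 15 liver genes silent in ATLD summed to at most 0.259 CPM, the other 4 being expressed in ATLD. Among those 4, Fgb reached only 0.2196 CPM in ATLD but averaged 23.4 CPM in the original WT libraries, and up to 33.9 CPM in the resequenced runs. The 9 of 15 muscle genes silent in ATLD summed to 0.8545 to 1.466 CPM in the original WT libraries and 0.8811 to 1.105 CPM in the resequenced runs. A gene silent in ATLD thus need not be silent in WT. The lung and immune transcripts touch the macrophage list and the level of Cd74 at WT day 0.

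Reads of a lung library carried into the original runs, or lung and immune cells in the cultures, could give this. The resequenced runs labelled as the same cultures held 13.22%, 9.28% and 6.59% of the original's summed CPM of lung epithelial genes and at most 2.58% of that of immune genes, where cells would give over 50%, which argues against cells. Carried-over reads stay open, since their test asked for under 10% in all 3 cultures and 1 missed it. Both bounds were written after the pattern was seen and changed after these shares were known. The 10% was loosened to 25% and then restored for carried-over reads, and for cells the bound that excludes them went from 10% to 25%, back to 10% and then to the 50% that cells need.

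Over 55% of the genes tested differed between ATLD and WT at day 0. Over the 10483 genes, the resequenced minus original log2 level of a WT culture held a median of -1.69%, -1.95% and 1.93% of the difference between genotypes in the cultures of day 0, day 14 and day 28, and over 50% of it for 2.89%, 13.75% and 2.85% of the genes. These genes were called in the fit with the batch term, which favours a low share, so the shares do not decide on batch. Over all genes tested, the resequenced runs of day 0, day 14 and day 28 had Pearson correlations of 0.9911, 0.98 and 0.9935 with their originals. With the ATLD libraries, of the same second batch, the highest were 0.9629, 0.9367 and 0.9421, which argues against sequencing batch as the whole cause. The slope of log2 CPM on log2 gene length was 0.075 to 0.251 in the WT libraries, resequenced ones included. In the ATLD libraries it was -0.375 to -0.079, so the length trend went with genotype, and its cause was not tested. With the GC and length trends removed 12040 were called, 8570 shared, which argues against these trends as the whole cause. Within 20 Mb of Mre11a lie 188 of the genes tested and 1.03% of the called genes. With 188 genes there, the share had to be small whatever the cause, so it does not decide on genes carried along with the allele. Effects of such genes on genes elsewhere were not tested. A difference of line or animal other than the allele cannot be told apart from an effect of the allele, since the design holds no further line. Of the genes within 20 Mb 57.45% were called and elsewhere 55.61% (Fisher's exact test, two-sided, p = 0.658).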
